A study of Mus musculus with 24 samples.

How the data were processed

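RNA was measured in mammary tumours of female neu-N mice, an FVB strain tolerant to the neu antigen, which had received NT2.5 tumour cells in the mammary fat pad. Per the labels, treatment began 3 days after implantation and lasted 3 weeks, with entinostat (ENT, an inhibitor of class I histone deacetylases) at 5 mg/kg by mouth each day and antibodies to PD-1 (PD1), CTLA-4 (CTLA4) or HER2 at 100 µg per mouse. Vehicle mice received isotype antibodies and methylcellulose. The 24 samples were vehicle, ENT, ENT+PD1, ENT+CTLA4 and ENT+PD1+CTLA4 with 4 each, ENT+CTLA4+HER2 with 2, and a further 2 whose titles repeat those of ENT+PD1 replicates 1 and 2 (the repeat-titled pair). The labels name whole tumours as the source, while the extraction protocol ends on the isolation of immune cells, and which of these went into the RNA was not settled here. The protocol also states that all studies in these mice were done with and without anti-HER2, and samples were grouped by their titles alone. The labels do not say that the samples of a group come from separate animals beyond separate tumours, so each p-value measures the spread between these samples.

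Counts of single RNA molecules came from an nCounter instrument. The series title and the table name the mouse PanCancer Immune panel, and the label protocol names a myeloid panel. The genes of the table were used as they stand: 750 endogenous and 20 housekeeping genes, with 8 negative and 6 positive control probes. Limma is the only tool named, per the submitters' processing notes, and its role, its version and the normalization are not given in the sources used here. The deposited values were read as normalized signal on a linear scale, since every sample had the same housekeeping geometric mean (346.9). Dividing each sample by a single factor returned whole numbers for 100% of the values above 1 (tolerance 0.05), so the deposited table also holds the counts up to that factor, and no subtraction of background was visible. The exceptions are 82 values at exactly 1, which were read as weaker values raised to 1. The control probes were unscaled counts per the file headers.

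Recovered totals over the genes averaged 364411 ± 70740 (SD, n = 24), from 226863 to 483418. They were 330572 ± 93560 in vehicle, 395155 ± 36810 in ENT, 392124 ± 67674 in ENT+PD1, 402550 ± 59230 in ENT+CTLA4, 377758 ± 62586 in ENT+PD1+CTLA4, 307268 ± 50762 in the repeat-titled pair and 269342 ± 60075 in ENT+CTLA4+HER2. The scaling factor was 1.50 ± 0.289 in ENT+CTLA4+HER2 and 0.939 ± 0.123 in ENT+CTLA4. Between 448 and 623 genes per sample had a normalized value of at least 20, and the 10 strongest genes took 42.8% of the counts on average.

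Per the file headers, the samples ran on 2 cartridges of 12. The first held vehicle, ENT and ENT+PD1, and the second held ENT+CTLA4, ENT+PD1+CTLA4, ENT+CTLA4+HER2 and the repeat-titled pair. Comparisons of an anti-CTLA-4 arm with vehicle, ENT or ENT+PD1 therefore cannot separate treatment from cartridge, and only the repeat-titled pair carries a treatment name found on both.

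Genes with a normalized value of at least 20 in at least 4 samples were tested, which kept 621 of 770 and left out 149. Values were taken as log2(value + 1), a scale that understates the fold change of weak genes. A single limma fit over 22 samples in 6 groups (lmFit, eBayes with trend) gave 10 comparisons, the interaction of anti-PD-1 with anti-CTLA-4 on entinostat, and an F test across 5 arms. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The repeat-titled pair was left out of these fits because its identity is open. No cartridge term entered, since it cannot be estimated without that pair. Replicate numbers did not enter as pairs: over 40 pairs of samples with the same number the median correlation was −0.033.

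For each comparison the genes named were the 10 largest rises and 10 largest falls among those called, up to 4 called members of each gene list, and, where fewer than 5 were called, the 5 with the smallest unadjusted p, said not to pass. The genes available in any comparison were Pdcd1, Cd274, Ctla4, Cd8a, Cd8b1, Cd4, Foxp3, Gzmb, Prf1, Ifng, Arg1, Nos2, Itgam, Cybb, S100a8, S100a9, Ncr1, Hdac3, Stat3, H2-Ab1 and Cxcl9. The rule, the groups, the tests and 23 gene lists were fixed before the data were examined. Of the genes the rule selects, 3 are not reported here, though they stayed in every test and adjustment where the filter kept them, and counts of named genes leave them out. The lists were tested with camera at a preset correlation of 0.01 against the other genes kept, with Benjamini-Hochberg adjustment over the lists of a comparison. A list needed at least 5 members kept, and mast cells were left untested for that reason. Because camera with an estimated correlation is stricter, its adjusted p is given wherever it does not call the list. A count "adjusted over the list alone" repeats the adjustment over the members of that list. Genes whose samples in 1 group all lay on one side of all samples of the other were counted as separated. A log2 change is left out where fewer than 2 of the 4 samples of the lower group exceeded the mean of the scaled negative controls by 2 SD, a rule set after the data were seen, since the size of such a change is not measured.

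Alternatives were no filter, a filter at 50, a pseudocount of 20, rescaling by housekeeping genes or by the median, quantile normalization, eBayes without trend, a fit of the compared groups alone, a replicate block, a block for the style of the sample code, the repeat-titled pair added to ENT+PD1, sample weights, each sample left out in turn, edgeR (quasi-likelihood) and DESeq2 on the recovered counts, and, for lists, camera with an estimated correlation and fry. Chosen after the data were seen were a cartridge block with the repeat-titled pair placed in ENT+PD1, a common floor of 20, endogenous genes only, and weights estimated gene by gene. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. The procedure was tested on simulated data with 200 of 621 genes changed. With 4 samples a side it recovered 33.3% of 1.5-fold, 67.3% of 2-fold and 95.5% of 4-fold changes (3.56% of calls false), and for ENT+CTLA4+HER2 against ENT+CTLA4 21.3%, 56.3% and 91.6% (4.01% false). With no change simulated it called 0 genes. The simulation lacks variation shared by many genes of a sample, which these tumours show. Gene symbols matched the reference by transcript for 746 genes and by symbol for 17, and 7 stayed unmatched and kept the symbol of the table.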

Results

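Tumours given entinostat with anti-PD-1 carried more transcript for the NKG2D receptor and for arginase 2 than tumours given entinostat alone, and anti-HER2 on top of entinostat and anti-CTLA-4 went with higher MHC class I and NK gene lists. Both of these comparisons lay within a cartridge, but their gene calls fell to 0 under median rescaling and under quantile normalization. All called genes kept their direction under both scalings. For anti-HER2 the median size of the 14 called genes was then 1.14 and 0.97 log2 units, left of 1.25. That median includes Cd160, Klrb1 and Ifna4, whose size is not measured. For anti-PD-1 no median is given, since 1 of the 2 called genes, Klrk1, lay at the level of the negative controls in ENT. Leaving out single samples could bring either count of calls to 0. The lists with anti-HER2 had a camera adjusted p = 0.671 with an estimated correlation. The NK mean there includes Klra6, whose size of change is not measured. Over all comparisons, 68 of 100 regroupings of the samples of the other arms gave at least the 22 list calls seen. Klrb1, Cd160, Ifit1 and Nod2 were lower in ENT+CTLA4 and in ENT+PD1+CTLA4 than in vehicle, which ran on the other cartridge, so that treatment and cartridge cannot be told apart. Across vehicle and the 4 entinostat arms without anti-HER2, the limma F test called 20 genes (121 at unadjusted p under 0.05; edgeR 9, DESeq2 48), led by Klrb1, an NK cell lectin receptor (adjusted p = 0.00292), and Cd160, a receptor of NK and cytotoxic T cells (adjusted p = 0.00461). Values are mean ± SD normalized counts with n = 4 per group, 2 for ENT+CTLA4+HER2, and log2 changes are given ± SE.

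**Figure D1:**
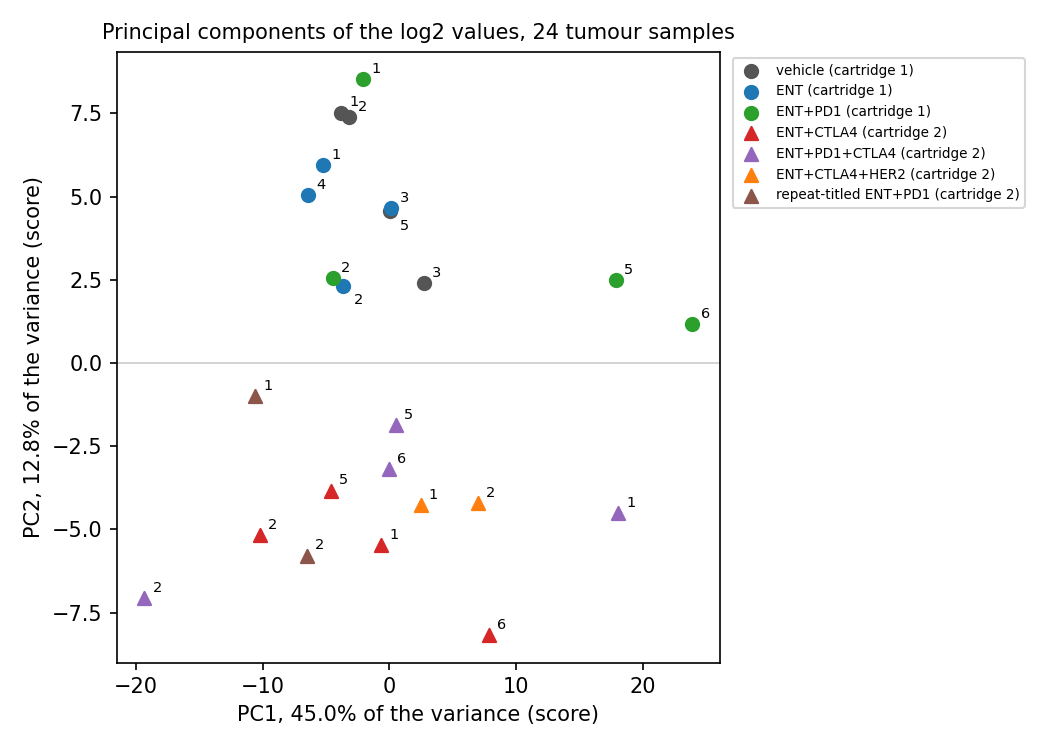
First and second principal components of the log2 values of 24 samples, coloured by group, with replicate numbers, circles for the first cartridge and triangles for the second. The line at 0 on the second component lies between the cartridges.

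The largest axis of variation was mainly one of immune signal. It took 45.0% of the variance, with the chemokines Ccl24 and Ccl8 and the T cell genes Icos and Cd3g at one end (loadings 0.117 to 0.141). The other end had weak loadings, led by Dmbt1, Bst1 and Nt5e (−0.035 to −0.026). The epithelial genes Itgb4, Epcam and Cdh1 came after them (−0.026 to −0.018). All these names were chosen after the values were seen. Samples of the same arm lay far apart on it: ENT+PD1+CTLA4 replicate 1 scored 18.0 and replicate 2 −19.3, and ENT+PD1 replicates 5 and 6 scored 17.9 and 23.9. The second axis (12.8%) separated the cartridges completely, with 1.17 as the lowest score on the first and −1.01 as the highest on the second.

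Several genes of T cells and cytotoxic effectors were too weak to test. Pdcd1, which encodes PD-1, the target of an antibody given, had a median of 10.8 over the 24 samples and exceeded the mean of the negative controls by 2 SD in 11 of them. The CD8 chains Cd8a and Cd8b1 had medians of 4.58 and 4.15 (2 samples each), the cytotoxic effectors Gzmb and Prf1 5.78 and 5.01 (1 and 2 samples) and the regulatory T cell factor Foxp3 7.58 (5 samples). None of these 6 genes entered a test, and S100a9 was not on the table. Cd4, of helper T cells, had a median of 9.97, the cytokine Ifng 11.4, the NK receptor Ncr1 12.8 and Ctla4 30.3.

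Entinostat alone gave no gene past the threshold against vehicle. The deacetylase Hdac3, which is among the housekeeping genes used for scaling, was 440 against 458 in vehicle, the signalling factor Stat3 1462 against 1559, and Arg1, the arginase of suppressive myeloid cells, 184 against 191. Cd274, which encodes PD-L1, was 35.5 ± 12.8 against 51.6 ± 23.9 (log2 change −0.47 ± 0.43), and the granulocyte alarmin S100a8 379 ± 75.1 against 524 ± 75.3. The lowest unadjusted p belonged to Ticam1, the TRIF adaptor of Toll-like receptors 3 and 4, at 27.9 ± 3.72 against 45.6 ± 6.01 (−0.69 ± 0.17, adjusted p = 0.456). Also among the 5 lowest were Alas1, of haem synthesis and also among the housekeeping genes (74.6 ± 2.58 against 101 ± 8.04), the kinase Ikbke (43.1 ± 4.25 against 60.1 ± 4.92) and Nod1, a sensor of bacterial cell wall (70.8 ± 7.40 against 104 ± 13.6), and none of these 4 passed. Limma called 0 of 621 genes (29 at unadjusted p under 0.05; edgeR 0, DESeq2 0). Samples were separated at 40 genes (6.44%, with 2.86% expected by chance). Simulated changes of 2-fold were recovered for 67.3% of genes, but with 200 of 621 genes changed and without variation shared by many genes. With so many changed genes the adjusted threshold is easier to pass. A case with few changed genes was not simulated, so effects of 2-fold could be missed as well as smaller ones.

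No gene list differed between ENT and vehicle. The lowest adjusted p was that of macrophages and monocytes (camera, 0.208). Of the suppressive myeloid genes, 16 of 18 were lower, with a mean of −0.15 (adjusted p = 0.876) that became −0.01 under median rescaling and −0.02 under quantile normalization, as were 9 of 10 neutrophil genes (mean −0.33, adjusted p = 0.789) and 12 of 14 MHC class I genes (mean −0.25, adjusted p = 0.789). Adjusted over the list alone, 1 of 25 Toll-like receptor and innate genes was lower, Ticam1. The median of all genes was itself shifted by −0.11.

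Macrophage and MHC class II genes were higher with entinostat and anti-PD-1 than with vehicle as groups of genes, by camera at the preset correlation only. With an estimated correlation neither list was called (adjusted p = 0.936 each), and no single gene passed. The rises lay in 2 of the 4 tumours: replicates 5 and 6 scored 1.07 and 1.59 for macrophages and 1.80 and 2.01 for MHC class II relative to vehicle, and replicates 1 and 2 −0.11 and 0.03, and −0.10 and −0.08. All 15 macrophage and monocyte genes were higher, by 0.64 on average (camera adjusted p = 0.00656, adjusted p = 0.936 with an estimated correlation). All 10 MHC class II genes were higher, by 0.91 (adjusted p = 0.0153, adjusted p = 0.936 with an estimated correlation). The class II beta chain H2-Ab1 was 5348 ± 4461 against 1792 ± 521, an SD that shows how far the 4 tumours differed. Epithelial and tumour genes were lower against the other genes (6 of 10 lower, mean −0.09, adjusted p = 0.0153, adjusted p = 0.320 with an estimated correlation), and so were cell cycle and survival genes (6 of 11 lower, mean −0.03, adjusted p = 0.0405, adjusted p = 0.268 with an estimated correlation). With single samples left out, the epithelial mean ran from −0.14 to −0.04. The cell cycle mean ran from −0.06 to 0.02, changing sign. No member of these 4 lists was called over all genes or adjusted over the list alone. The median of all genes moved by 0.18.

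Cd69, Itgb3, Arg2, Trp53 and Psmb10 came closest to the threshold in ENT+PD1 against vehicle. Cd69, an early activation marker of lymphocytes, was 121 ± 59.8 against 45.3 ± 23.9 (1.37 ± 0.39), the mitochondrial arginase Arg2 82.8 ± 32.1 against 38.6 ± 9.12, and Psmb10, a subunit of the immunoproteasome, 66.6 ± 13.0 against 43.8 ± 8.59. The integrin Itgb3 was 190 ± 22.8 against 235 ± 14.9, and the tumour suppressor Trp53 140 ± 22.4 against 180 ± 16.6. None of the 5 passed (adjusted p = 0.470 each). Arg1 was 485 ± 310 against 191 ± 64.1 and Cd274 106 ± 70.8 against 51.6 ± 23.9, also short of the threshold. Limma called 0 genes (60 at unadjusted p under 0.05; edgeR 0, DESeq2 0), and 16 genes were separated (2.58%, with 2.86% expected by chance). T cell genes (10 of 10 higher, mean 0.64) and dendritic cell genes (10 of 11, mean 0.64) were not called (adjusted p = 0.645 and 0.135).

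Adding anti-PD-1 to entinostat raised the transcripts of an activating receptor and of an arginase. Klrk1, which encodes NKG2D, the activating receptor of NK and CD8 T cells, rose from 7.83 ± 2.84 to 26.0 ± 10.7 (limma adjusted p = 0.0400). Arg2 rose from 27.8 ± 11.3 to 82.8 ± 32.1 (1.54 ± 0.32, adjusted p = 0.0400). The level of Klrk1 in ENT was that of the scaled negative controls (7.48), so the size of its rise is not measured. Both calls were lost in edgeR (adjusted p = 0.102 each), under median rescaling (0.272 each), with a floor of 20 (0.164 for Klrk1 and 0.0870 for Arg2), and when any of 5 samples was left out. MHC class II genes rose as a list through replicates 5 and 6, which exceeded 1 and 2 by 1.99 (10 of 10 higher, mean 1.08, camera adjusted p = 0.0366, adjusted p = 0.877 with an estimated correlation). All samples of both groups ran on the same cartridge, and both called genes were separated.

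Other genes had higher values in ENT+PD1 than in ENT without passing. Batf, a transcription factor of activated lymphocytes, was 45.5 ± 20.1 against 18.2 ± 4.15 (adjusted p = 0.0705), the housekeeping gene Alas1 115 against 74.6 (0.0640) and Ikbke 67.4 against 43.1 (0.143). Cd274 was 106 ± 70.8 against 35.5 ± 12.8 (1.34 ± 0.43, adjusted p = 0.205), Arg1 485 ± 310 against 184 ± 23.8 (0.214), the phagocyte oxidase subunit Cybb 462 against 218 (0.227), the myeloid integrin Itgam 142 against 70.6 (0.242) and Ctla4 97.4 against 24.6 (0.254). Limma called 2 genes (120 at unadjusted p under 0.05; edgeR 0, DESeq2 1), and 44 were separated (7.09%, with 2.86% expected by chance). The epithelial list was called lower (camera adjusted p = 0.0351, adjusted p = 0.382 with an estimated correlation) although its mean was 0.03 and its median −0.09, and the mean became −0.33 under median rescaling. The housekeeping list was called lower at a mean of 0.00 (adjusted p = 0.000364), which follows from scaling every sample to those genes while the median of all genes moved by 0.34. Adjusted over the list alone, 2 Toll-like receptor and innate genes and 1 type I interferon gene differed.

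**Figure D2:**
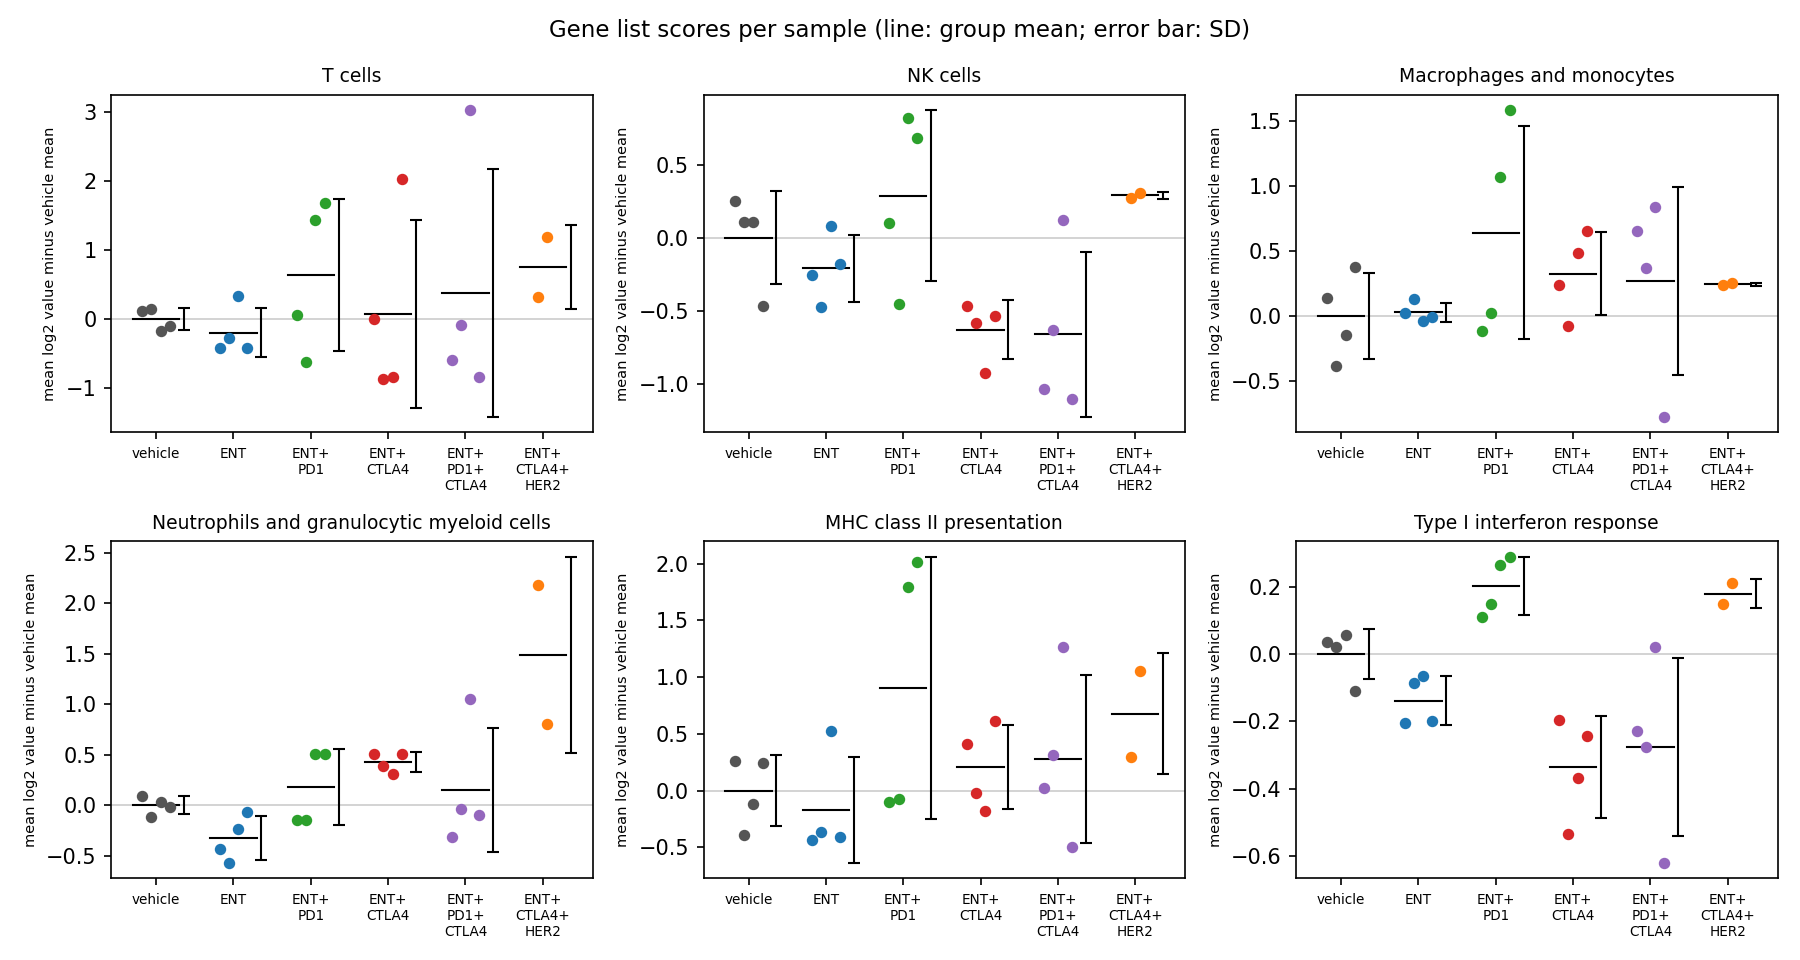
Mean log2 value of the genes of 6 lists in each sample, relative to the vehicle mean, by group, with the group mean and SD. The samples of ENT+PD1 spread widely for T cells and MHC class II.

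With entinostat and anti-CTLA-4, 9 genes were lower than in vehicle, among them Klra6, Cd160, Klrb1, Xcr1, Usp18 and Ifit1. Klra6, an inhibitory Ly49 receptor of NK cells, fell from 24.6 ± 7.69 to 5.64 ± 2.64 (limma adjusted p = 0.0126), Cd160 from 23.4 ± 4.07 to 6.70 ± 2.22 (0.0117) and Klrb1 from 20.8 ± 6.54 to 7.19 ± 0.144 (0.0126). Xcr1, the chemokine receptor of cross-presenting dendritic cells, fell from 25.7 ± 10.7 to 8.08 ± 4.03 (0.0368), and Ptgdr2, a prostaglandin D2 receptor of type 2 lymphocytes, from 23.1 ± 4.05 to 8.32 ± 2.63 (0.0368). Gpr44, an older symbol of the same receptor, is a separate entry and was named after its values were seen. The F test did not call it (adjusted p = 0.152, against 0.0423 for Ptgdr2). Usp18, a brake on interferon signalling, fell from 28.1 ± 10.8 to 11.4 ± 4.25 (0.0368) and the interferon-induced Ifit1 from 36.7 ± 8.28 to 15.8 ± 2.19 (0.0307). The peptidoglycan sensors Nod2 (28.7 ± 1.81 to 13.6 ± 3.31, adjusted p = 0.0422) and Nod1 (104 ± 13.6 to 58.7 ± 9.69, adjusted p = 0.0368) fell too. Ly49 probes bind a family of near-identical genes, so the identity of Klra6 is uncertain. In ENT+CTLA4, Klra6, Cd160, Klrb1, Xcr1 and Ptgdr2 each exceeded the scaled negative controls (mean 4.69) by 2 SD in 0 or 1 of 4 samples, so the size of their fall is not measured.

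These were the only genes called, 9 of 621, all lower and all separated (103 at unadjusted p under 0.05), with 9 called by edgeR and 21 by DESeq2. Median rescaling called 12 genes and quantile normalization 0, and all 9 kept their direction under both. Their median size is left out, since the size is not measured for most of them. Leaving out vehicle replicate 5 or 1 left 0 calls, and 6 of 8 such fits moved the count by more than 1.5 times. A fit of the compared groups alone gave 0. Across all genes, 79 were separated (12.7%, with 2.86% expected by chance). Most of the called genes lay near the negative controls in the anti-CTLA-4 arms, and the 2 groups ran on different cartridges. With the cartridge as a block, tied only through the repeat-titled pair, 0 genes were called. The block takes the cartridge effect as that pair minus all 4 ENT+PD1 tumours, of which replicates 5 and 6 were rich in immune transcripts. Random lists of genes differed in the pair by −0.73 from ENT+PD1 and by −0.16 from ENT. The block can therefore lift genes of the second cartridge too far. Its results across cartridges do not separate treatment from cartridge. Of the genes whose size is measured, Ifit1 went from −1.14 to −0.09 and Nod1 from −0.82 to −0.21 with the block. Usp18 went from −1.22 to 0.28 and Nod2 from −1.05 to 0.59.

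**Figure D3:**
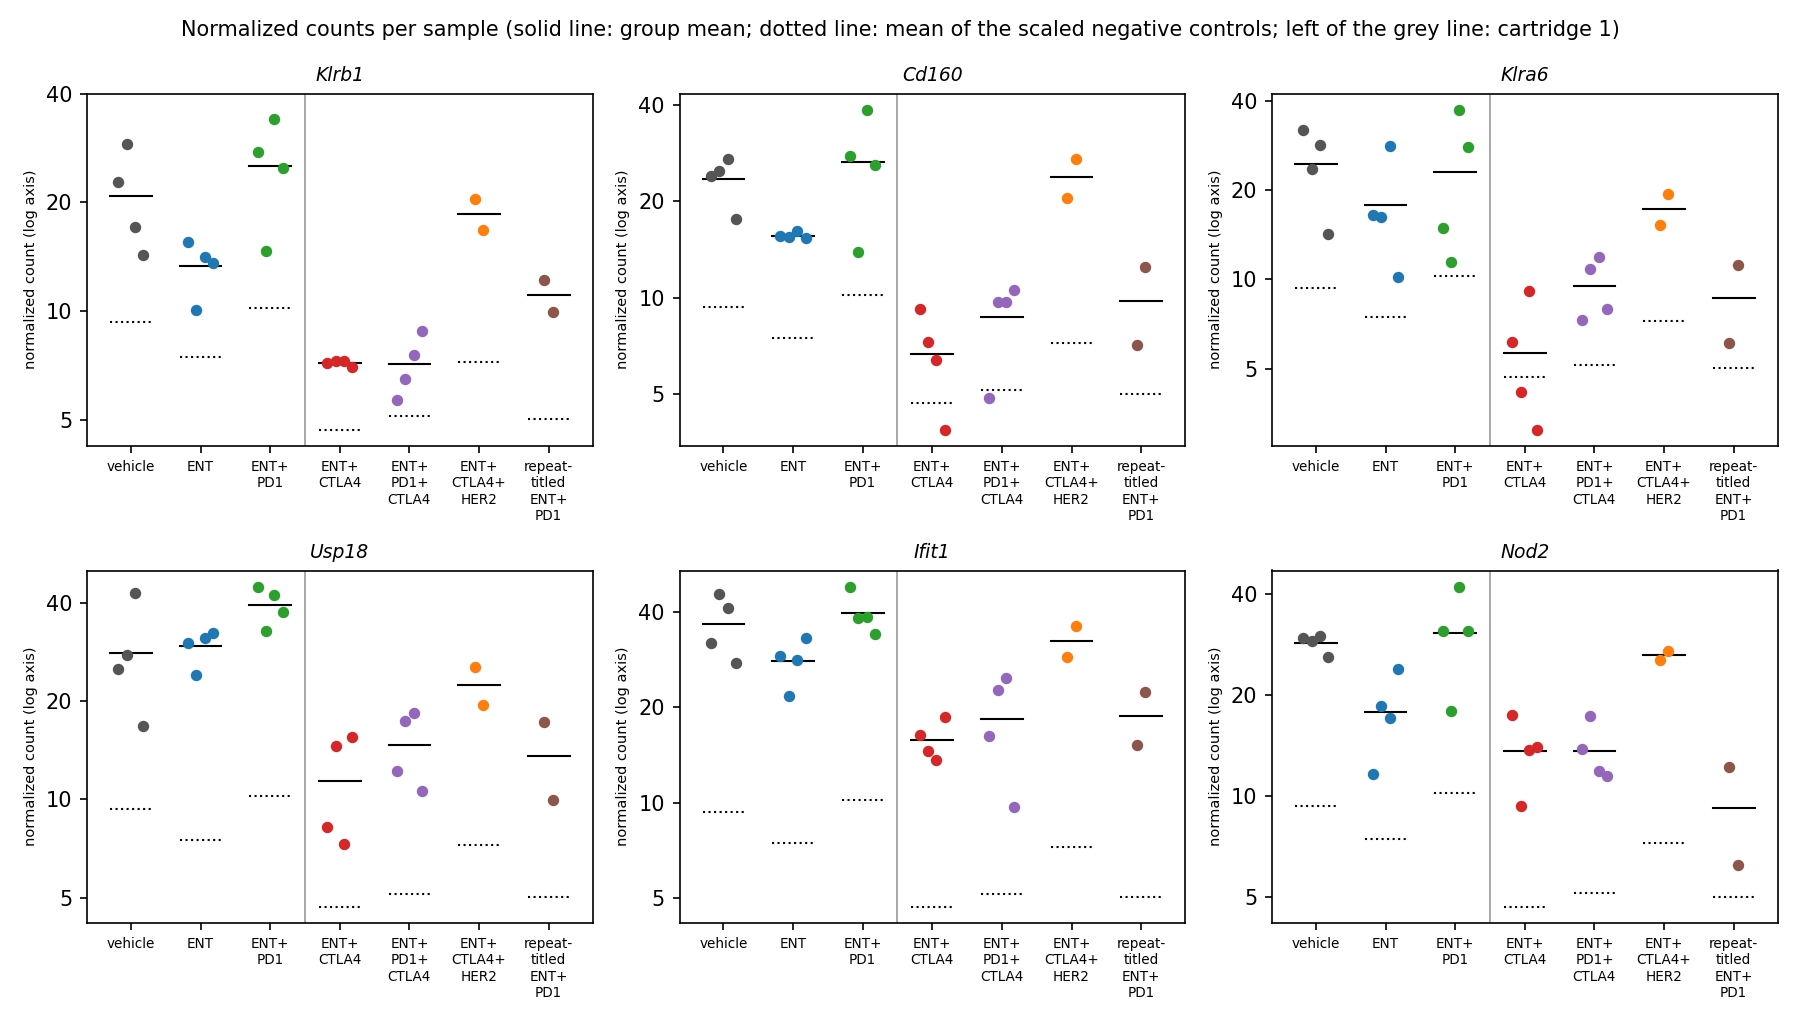
Normalized counts of Klrb1, Cd160, Klra6, Usp18, Ifit1 and Nod2 in each sample of 7 groups on a log axis, with group means as solid lines and the mean of the scaled negative controls as dotted lines. The grey line separates the first cartridge from the second.

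By camera at the preset correlation, NK and interferon genes were lower as groups, and myeloid genes higher, in ENT+CTLA4 than in vehicle. None of these lists was called with an estimated correlation. Over all comparisons, 68 of 100 regroupings of the samples, the real one included, gave at least the 22 list calls seen. NK genes were lower at 8 of 10 (mean −0.63, camera adjusted p = 0.0490, 1 member called, 3 adjusted over the list alone) and type I interferon genes at 19 of 22 (mean −0.34, adjusted p = 0.0389, 2 called, 3 adjusted over the list alone). All of the 10 NK members but Ncr1, Klrc1 and Il2rb were Ly49 probes, so they are not 10 separate measurements in any comparison. The called member, Klra6, lay near the negative controls, so the NK mean includes a change whose size is not measured. Macrophage genes were higher at 14 of 15 (mean 0.33, adjusted p = 0.00751) and neutrophil genes at 9 of 10 (mean 0.43, adjusted p = 0.00834), with no member called. With single samples left out, the macrophage mean ran from 0.20 (vehicle replicate 1) to 0.46 (ENT+CTLA4 replicate 2). All 4 had an adjusted p = 0.969 with an estimated correlation, and under quantile normalization the NK mean was −0.19 and the interferon mean −0.15. With the cartridge block the NK list (camera adjusted p = 0.924) and the neutrophil list (0.783) were no longer called. The interferon list turned higher (0.783), while the macrophage list stayed (9.95e-05). The block does not decide these either, since its term is the repeat-titled pair minus ENT+PD1. Their mean macrophage scores were −0.25 and 0.64. MHC class I genes were lower at 11 of 14 (mean −0.32, adjusted p = 0.259), 4 of them adjusted over the list alone. S100a8 was 1044 ± 370 against 524 ± 75.3 (adjusted p = 0.411) and Nos2, the inducible nitric oxide synthase, 22.2 against 36.9 (0.0927).

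Against ENT, the ENT+CTLA4 tumours carried more neutrophil transcript as a list. Of 10 neutrophil and granulocytic genes 9 were higher, by 0.76 on average (camera adjusted p = 0.00085, adjusted p = 0.941 with an estimated correlation), 0 of them called over all genes and 6 adjusted over the list alone. With the cartridge block the list was not called (adjusted p = 0.392). S100a8 was 1044 ± 370 against 379 ± 75.1 (1.41 ± 0.54, adjusted p = 0.239), and Clec5a, a lectin receptor of myeloid cells, 176 ± 20.5 against 81.9 ± 23.4 (1.13 ± 0.28, adjusted p = 0.104). Usp18 was 11.4 ± 4.25 against 29.4 ± 3.74 (−1.35 ± 0.28, adjusted p = 0.0747), Klra6 5.64 ± 2.64 against 17.8 ± 7.54 and Cd160 6.70 ± 2.22 against 15.6 ± 0.353 (0.104 each). None of these passed. Limma called 0 genes (94 at unadjusted p under 0.05; edgeR 0, DESeq2 15), against 46 in a fit of the compared groups alone, 114 were separated (18.4%, with 2.86% expected by chance), and the groups ran on different cartridges.

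With both antibodies on entinostat, 13 genes were lower than in vehicle, among them Klra7, Klrb1, Cd160, Oas3, Ifit1 and Nos2. Klra7, another Ly49 receptor with the same uncertainty of identity, fell from 17.0 ± 5.89 to 3.47 ± 4.89 (limma adjusted p = 0.0357), with 3 of 4 samples at 1.00 to 1.08 and a mean under that of the scaled negative controls (5.14), so the size of the fall is not measured. Klrb1 fell from 20.8 ± 6.54 to 7.14 ± 1.36 (0.0238), Cd160 from 23.4 ± 4.07 to 8.73 ± 2.60 (0.0355) and Sh2d1b1, a signalling adaptor of NK cells, from 26.6 ± 7.71 to 10.9 ± 2.94 (0.0357). Gfi1, a repressor in blood cell development, fell from 20.2 ± 5.10 to 7.59 ± 3.83 (0.0412), the receptor kinase Ltk from 25.9 ± 7.37 to 10.1 ± 3.83 and the antiviral synthetase Oas3 from 20.7 ± 5.24 to 8.03 ± 2.97 (0.0357 each). In ENT+PD1+CTLA4, Klrb1 and Oas3 exceeded the scaled negative controls by 2 SD in 0 of 4 samples, and Cd160 and Gfi1 in 1 of 4. The size of the falls of these genes is not measured either. Ifit1 (36.7 ± 8.28 to 18.4 ± 6.85), Nod2 (28.7 ± 1.81 to 13.6 ± 2.66) and Bcl6, a repressor of germinal centre cells (131 ± 14.2 to 85.0 ± 14.8), fell at an adjusted p = 0.0357. Nos2 fell from 36.9 ± 7.22 to 18.2 ± 3.07 (−0.98 ± 0.21, adjusted p = 0.0355) and Alas1 from 101 ± 8.04 to 63.3 ± 4.77 (0.0316).

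Limma called 13 genes here, all lower (88 at unadjusted p under 0.05; edgeR 0, DESeq2 0), and 0 under median rescaling or quantile normalization, where the median size of the 13 went from 1.20 to 1.22 and 0.88. The remaining one, Vhl, which encodes part of a ubiquitin ligase of oxygen sensing, lies outside the naming rule and was named after its values were seen (adjusted p = 0.0357). Leaving out vehicle replicate 5 left 0 calls, and 6 of 8 such fits moved the count by more than 1.5 times. Of the 13, 12 were separated, and 53 of all genes were (8.53%, with 2.86% expected by chance). Macrophage genes were higher at 15 of 15 (mean 0.27, camera adjusted p = 0.0329, adjusted p = 0.946 with an estimated correlation), with 0 called, and the mean was 0.09 without replicate 1 and 0.62 without replicate 2. NK genes were lower at 8 of 10 (mean −0.66, adjusted p = 0.0586, 1 called, 5 adjusted over the list alone) and endothelial and stromal genes at 17 of 17 (mean −0.38, adjusted p = 0.218). The stromal mean came from replicate 2, with a score of −1.80 against 0.27, −0.13 and 0.13 in the others. Arg1 was 302 ± 87.6 against 191 ± 64.1, without passing. The groups ran on different cartridges, and with the cartridge block 0 genes were called and the median change of the 13 went from −1.20 to −0.32. That median includes Klra7, Klrb1, Cd160, Oas3 and Gfi1, whose size is not measured. The NK mean includes Klra7 too.

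Against ENT the same triple arm showed no called gene. Hmgb1, a nuclear protein released as an alarmin, was 461 ± 33.3 against 634 ± 27.7 (−0.46 ± 0.11), Oas3 8.03 against 19.9, Gfi1 7.59 against 19.7 and Arg2 64.4 ± 23.5 against 27.8 ± 11.3 (1.21 ± 0.32), each at an adjusted p = 0.208. Limma called 0 genes (70 at unadjusted p under 0.05; edgeR 0, DESeq2 0), with 61 separated (9.82%, with 2.86% expected by chance). NK and neutrophil lists reached an adjusted p of 0.0560 each, neutrophil genes with 8 of 10 higher (mean 0.48, 2 adjusted over the list alone).

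Adding anti-CTLA-4 to entinostat and anti-PD-1 went with 20 lower genes, among them Klrb1, Cd160, Tigit, Usp18 and Ifit1. Klrb1 fell from 25.3 ± 8.01 to 7.14 ± 1.36 (limma adjusted p = 0.00213), Cd160 from 26.5 ± 10.1 to 8.73 ± 2.60 (0.0108), Sh2d1b1 from 31.7 ± 9.07 to 10.9 ± 2.94 (0.0108) and Klra7 from 22.6 ± 10.2 to 3.47 ± 4.89 (0.0116), and the size of these falls, except that of Sh2d1b1, is again not measured. Tigit, an inhibitory receptor of T and NK cells, fell from 39.2 ± 16.1 to 14.3 ± 6.68 (0.0488). Among interferon-induced genes, Usp18 fell from 39.2 ± 5.36 to 14.6 ± 3.82 (0.0108), Ifit1 from 39.9 ± 5.94 to 18.4 ± 6.85 (0.0153), the nucleotide kinase Cmpk2 from 46.2 ± 5.74 to 18.0 ± 9.52 (0.0234) and Oas3 from 23.7 to 8.03 (0.0211). Gfi1 (25.6 ± 6.26 to 7.59 ± 3.83, adjusted p = 0.0108), Ltk (27.6 to 10.1, adjusted p = 0.0168) and Nod2 (30.6 to 13.6, adjusted p = 0.0248) fell as well. Oas3 and Gfi1 exceeded the negative controls in 0 and 1 of 4 samples of ENT+PD1+CTLA4, so the size of their falls is not measured either. Smaller falls were those of Alas1 from 115 ± 25.7 to 63.3 ± 4.77 (−0.83 ± 0.13, adjusted p = 0.00213), of Nos2 from 32.6 ± 6.83 to 18.2 ± 3.07 (0.0488) and of Nfkbia, the inhibitor of NF-kB, from 1044 ± 124 to 705 ± 55.8 (−0.56 ± 0.15, adjusted p = 0.0488).

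In this comparison limma called 20 genes, all lower (110 at unadjusted p under 0.05; edgeR 1, DESeq2 0), against 0 under median rescaling and 1, a higher gene, under quantile normalization, where the median size of the 20 went from 1.28 to 1.08 and 0.63. Of the 20, 18 were separated, and 51 of all genes were separated (8.21%, with 2.86% expected by chance). NK genes were lower at 9 of 10 (mean −0.95, camera adjusted p = 0.0110, adjusted p = 0.702 with an estimated correlation, 1 called, 6 adjusted over the list alone). Type I interferon genes were lower at 18 of 22 (mean −0.48, adjusted p = 0.0791, 3 called, 8 adjusted over the list alone) and checkpoint genes at 17 of 20 (mean −0.58, adjusted p = 0.302, 2 called, 4 adjusted over the list alone). Under quantile normalization the means of these 3 lists were −0.22, −0.03 and −0.20. The housekeeping list was called higher (adjusted p = 0.00848), and its mean went from 0.00 to 0.20 under median rescaling, an effect of the scaling while the median of all genes moved by −0.25. The groups ran on different cartridges, and with the cartridge block 0 genes were called and the median change of the 20 went from −1.28 to −0.13. That median includes genes whose size is not measured. The NK list was not called with the block (camera adjusted p = 0.975). The NK mean includes Klra7, whose size of change is not measured.

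Within the second cartridge, adding anti-PD-1 to entinostat and anti-CTLA-4 gave no called gene. Arg1 was 302 ± 87.6 against 165 ± 55.8 (0.88 ± 0.41), without passing. The smallest unadjusted p belonged to Il1rap, a subunit of the interleukin 1 receptor (389 ± 17.4 against 454 ± 31.1), the MHC class I gene H2-Q2 (17.4 ± 4.98 against 9.60 ± 4.46), the TGF-beta receptor Tgfbr1 (344 ± 47.4 against 422 ± 32.5), the zinc finger gene Zfp13 (19.6 against 29.0) and the transcription factor Creb1 (110 against 133), and none passed (adjusted p = 1.00 each). Limma called 0 genes (10 at unadjusted p under 0.05; edgeR 0, DESeq2 0), and 9 were separated (1.45%, with 2.86% expected by chance). Neutrophil genes were lower at 9 of 10 (mean −0.28, camera adjusted p = 0.0364) and MHC class I genes higher at 12 of 14 (mean 0.17, adjusted p = 0.0364), with an adjusted p = 0.977 for both with an estimated correlation and 0 members called. Replicate 1 of the triple arm carried the MHC class I rise, whose mean was −0.01 without it. The neutrophil mean was −0.58 without that replicate and −0.13 without replicate 5 of the triple arm.

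Anti-HER2 added to entinostat and anti-CTLA-4 went with rises of Psmb9, Cd160, Sh2d1b1, Klrb1 and Ifna4 and, with a preset correlation only, of the lists of MHC class I, NK and interferon genes (lowest adjusted p = 0.671 with an estimated correlation). Psmb9, an immunoproteasome subunit that shapes peptides for MHC class I, rose from 48.8 ± 8.29 to 122 ± 4.45 (1.32 ± 0.31, limma adjusted p = 0.0344). Cd160 rose from 6.70 ± 2.22 to 23.8 ± 4.75 (0.0249), Sh2d1b1 from 12.2 ± 3.93 to 36.8 ± 0.870 (0.0251), Klrb1 from 7.19 ± 0.144 to 18.6 ± 2.55 (0.0472) and the interferon gene Ifna4 from 5.91 ± 3.75 to 26.5 ± 8.22 (0.0495). In ENT+CTLA4, Cd160, Klrb1 and Ifna4 each exceeded the scaled negative controls by 2 SD in 0 or 1 of 4 samples, so the size of their rise is not measured. The protease inhibitor A2m rose from 13.8 ± 10.8 to 69.0 ± 30.3 (2.46 ± 0.53, adjusted p = 0.0249). Csf3, the growth factor of granulocytes, rose from 95.4 ± 28.1 to 247 ± 150 (limma adjusted p = 0.0472). Tgfb2, a suppressive cytokine, rose from 65.4 ± 11.2 to 139 ± 61.4 (1.02 ± 0.22, adjusted p = 0.0249). The 2 anti-HER2 tumours differed widely for both genes, and ENT+CTLA4 replicate 1 had 137.49 for Csf3. The p-values rest on a spread shared by all groups.

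In the same comparison Ctsw, Mavs, Itgb4, Itgb3, Il34 and St6gal1 fell, while neither the epithelial list (mean 0.09, and −0.05 under quantile normalization) nor the CD8 T cell and cytotoxic list (mean 0.27, and −0.29 under quantile normalization) was called. Ctsw, a cathepsin of cytotoxic lymphocytes, fell from 136 ± 46.7 to 51.5 ± 1.65 (−1.32 ± 0.27, limma adjusted p = 0.0249), and Mavs, the adaptor of cytosolic RNA sensors, from 96.9 ± 7.99 to 57.1 ± 8.68 (−0.76 ± 0.15, adjusted p = 0.0249). The epithelial integrin Itgb4 fell from 1436 ± 191 to 771 ± 411 (limma adjusted p = 0.0472), with a wide difference between the 2 anti-HER2 tumours. Itgb3 fell from 201 ± 10.4 to 145 ± 7.38 (0.0454). The macrophage growth factor Il34 fell from 94.8 ± 4.08 to 55.8 ± 6.86 (0.0310) and the sialyltransferase St6gal1 from 423 ± 74.6 to 271 ± 52.2 (0.0472). The interferon-gamma chemokine Cxcl9 was 88.7 ± 38.9 against 13.3 ± 13.9 (3.22 ± 0.88, adjusted p = 0.0583), Nos2 41.7 against 22.2 (0.0801) and S100a8 6723 ± 7234 against 1044 ± 370 (0.0858), all short of the threshold.

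**Figure D4:**
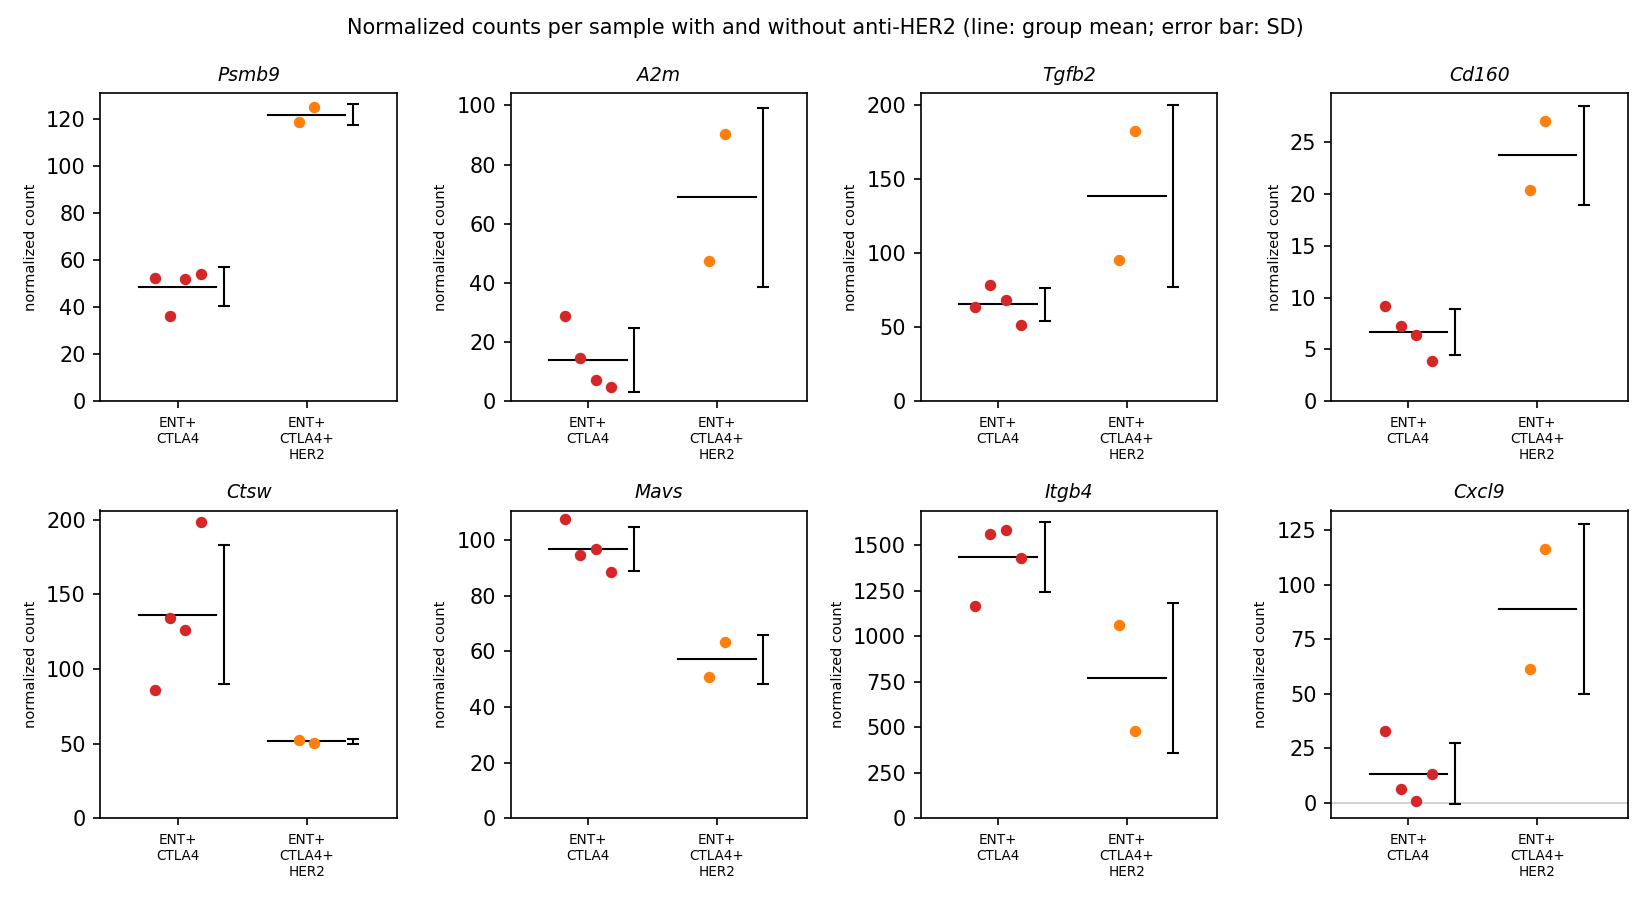
Normalized counts of Psmb9, A2m, Tgfb2, Cd160, Ctsw, Mavs, Itgb4 and Cxcl9 in ENT+CTLA4 (n = 4) and ENT+CTLA4+HER2 (n = 2), with mean and SD. All 6 samples ran on the second cartridge.

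Limma called 14 genes, 8 higher and 6 lower, all separated (117 at unadjusted p under 0.05; edgeR 16, DESeq2 23), against 0 under median rescaling, 0 under quantile normalization (median size 1.14 and 0.97 left of 1.25) and 0 with a block for the style of the sample code, and 179 of all genes were separated (28.8%, with 13.3% expected by chance). Leaving out ENT+CTLA4 replicate 5 left 0 calls. The median sizes include Cd160, Klrb1 and Ifna4, whose size is not measured. As groups, MHC class I genes were higher at 13 of 14 (mean 0.66, camera adjusted p = 0.00704, 1 called, 4 adjusted over the list alone), NK genes at 9 of 10 (mean 0.92, adjusted p = 0.0217, 3 adjusted over the list alone), type I interferon genes at 20 of 22 (mean 0.51, adjusted p = 0.0217, 2 adjusted over the list alone) and neutrophil genes at 10 of 10 (mean 1.06, adjusted p = 0.0357, 5 adjusted over the list alone). These 4 had an adjusted p = 0.671 with an estimated correlation, and under quantile normalization their means were 0.42, 0.32, 0.16 and 0.85. The NK mean includes Klra6, which exceeded the negative controls in 0 of 4 ENT+CTLA4 samples, so the size of its change is not measured. The scaled negative controls were themselves higher with anti-HER2 (7.24 ± 0.878 against 4.69 ± 0.842). The neutrophil mean was 0.37 without replicate 1 of the anti-HER2 arm and 1.75 without replicate 2. Interferon-gamma genes were higher at 11 of 14 (mean 0.80, adjusted p = 0.0357, 3 adjusted over the list alone), with an adjusted p = 0.836 with an estimated correlation. Suppressive myeloid genes, with Csf3 and Tgfb2 called and 4 adjusted over the list alone, were higher at 13 of 18 (mean 0.45, adjusted p = 0.222). The arm has 2 tumours, with larger scaling factors, and the median of all genes moved by 0.17.

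The effect of anti-CTLA-4 on entinostat was not shown to depend on anti-PD-1. Alas1 gave the lowest adjusted p (interaction −0.83 ± 0.19, adjusted p = 0.218), followed by Klrk1, Irak2, a kinase of interleukin 1 signalling (−0.84 ± 0.24), the Fc receptor Fcgr4 (−1.16 ± 0.33) and the chemokine Cxcl16 (−0.71 ± 0.22), each at 0.400. Limma called 0 genes (42 at unadjusted p under 0.05; edgeR 0, DESeq2 0), and of the lists only housekeeping genes passed, which the scaling fixes. A cartridge effect that adds to the log2 values of all arms alike cancels in this contrast. Over all 10 comparisons, 22 of 220 list tests passed with the preset correlation, 2 with an estimated correlation (both housekeeping genes) and 4 with fry, which tests a list against no change and not against the other genes, so that a shift of all genes enters it. Among those 4, fry gave an adjusted p = 0.0462 for NK genes in ENT+PD1+CTLA4 against ENT+PD1, where it also called type I interferon genes (0.00981), and 0.0297 for MHC class I and 0.0240 for type I interferon genes in ENT+CTLA4+HER2 against ENT+CTLA4.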

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

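Which tests were set after the result was seen is as follows: those of the cartridge, of anti-CTLA-4 as the whole cause, of a set effect and of larger counts followed the results they weigh, as did the comparisons with negative controls and random lists and the Fisher test, and the tests of tumour share and single tumours came before. Those of weak signal and of scaling were written before their results but rest on a floor of 20 chosen after the data were seen. Of 425 groups of 4 samples checked for a sample far from the other 3 (the highest or lowest by Dixon's ratio at 95%), 30 had one, or 7.06%, where chance flags about 1 in 20 groups. Each is given with the range of the other 3 samples in normalized counts.

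In vehicle, replicate 3 stood apart for Arg1 (287.18 against 151 to 166), Klra7 (8.4 against 18.6 to 21.7) and Gfi1 (12.6 against 21.7 to 23.5), replicate 2 for Ikbke (52.79 against 61.7 to 63.7) and replicate 5 for Il34 (119.89 against 97.0 to 99.9). In ENT, replicate 3 was high for H2-Ab1 (2828.78 against 1143 to 1326) and for the MHC class II list score (0.52 against −0.44 to −0.36), replicate 1 low for Arg1 (148.65 against 191 to 201) and high for Zfp13 (32.06 against 26.2 to 26.4). Replicate 2 of ENT was apart for Tigit (17.8 against 26.2 to 26.4) and Psmb9 (44.9 against 66.6 to 71.9), and replicate 4 for Batf (11.93 against 20.1 to 20.4) and Ctsw (214.7 against 148 to 155).

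In ENT+PD1, replicate 6 stood apart for Ncr1 (20.76 against 11.4 to 12.6) and Itgb4 (787.68 against 1141 to 1229), and replicate 1 for Stat3 (1283.36 against 1471 to 1505). In ENT+CTLA4, replicate 6 was apart for Ctla4 (30.29 against 17.4 to 18.8), Gfi1 (4.66 against 11.3 to 12.8), Il1rap (407.77 against 461 to 473) and the epithelial list score (−0.24 against 0.01 to 0.03), replicate 1 for Ikbke (53.36 against 59.0 to 59.4) and Csf3 (137.49 against 79.4 to 82.3), and replicate 2 for Psmb9 (36.45 against 52.0 to 54.4). In ENT+PD1+CTLA4, replicate 2 was low for Cybb (199.23 against 347 to 373), Fcgr4 (61.71 against 81.1 to 83.3) and Cxcl16 (448.72 against 634.8 to 650.5), and replicate 6 high for Arg2 (99.49 against 50.2 to 56.0). Replicate 5 of that arm was low for Cd160 (4.87 against 9.73 to 10.6), and replicate 1 high for Klra7 (10.81 against 1.00 to 1.08) and for the B cell list score (1.49 against −0.34 to −0.28).

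The housekeeping list differed by the test of the interaction itself (camera adjusted p = 0.000332), which the scaling of each sample to these genes accounts for, since the list keeps a fixed mean while other genes move. The repeat-titled pair, which no comparison of the report uses, had 3 genes called against vehicle by limma (77 at unadjusted p under 0.05): the receptor Igf2r was higher (0.60), and Bst2, an interferon-induced tetherin (−0.69), and Nod2 (−1.60) were lower. Both of these groups differ in cartridge as well.

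The first pattern weighed was the fall of 18 genes, 22 calls in all, in the arms with anti-CTLA-4 against the vehicle samples that both share, with a median of −1.15. This median includes genes whose size is not measured. The repeat-titled pair, on the same cartridge and titled without anti-CTLA-4, was lower than ENT at these genes by a median of −0.49 (−0.40 and −0.34 in the single samples, the smaller fall being −0.339). In the pair 15 of the 18 genes were lower than in ENT. Random lists gave −0.16, and 2% of them fell as far. They were drawn from genes below an upper limit of signal and were not matched for level. Treatment as the whole cause and the cartridge both stay open. Against ENT+PD1 the pair differed by −0.95, against −0.73 for random lists (8.42% of them fell as far), while ENT+CTLA4+HER2, on that cartridge too, was higher than ENT by 0.40. Signal near the background stays open as well: negative controls averaged 8.65 ± 1.17 counts on the first cartridge and 5.01 ± 0.568 on the second (n = 12 each, permutation p = 1e-05, the smallest that 100000 resamples can give), and 3 of the 22 calls remained with values under 20 raised to 20, which decides nothing because 18 of the 22 had a vehicle mean under 40 and would lose a real fall too. Of the 18 genes, 14 (77.8%) had a mean under 50, against 34.1% of all genes (Fisher exact p = 0.000157), and what remains open is whether anti-CTLA-4 adds to this, since no arm was run on both cartridges under a settled name.

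The second pattern was the gap within ENT+PD1, where replicates 5 and 6 exceeded 1 and 2 by 1.83 for T cell genes, 1.99 for MHC class II and 1.37 for macrophages. A set effect of samples coded with a number only stays open: the same split of T cell and MHC class II genes gave 0.52 in ENT+CTLA4 and −0.82 in ENT+PD1+CTLA4, and the latter became 0.58 without replicate 1. Larger raw counts are argued against, since the lowest total of replicates 5 and 6 minus the highest of 1 and 2 was −105369 counts. These totals do not test the amount of signal relative to the housekeeping genes used for scaling. With a lower share of tumour cells as the whole cause, the lists of other cells would rise alike. They rose unequally, T cells exceeding endothelium and stroma by 1.26 (SE 0.309 over the genes of the lists). That SE holds no spread between tumours, so the gap describes these tumours and does not settle the cause. More immune infiltrate in some tumours than in others of the same arm may be the reason, and no biological explanation was tested, as no label tells these tumours apart.

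The third pattern was the rise of interferon and MHC class I genes with anti-HER2, by 0.64 on average over 50 genes, 44 of them higher. A single tumour is argued against, since leaving out either left 0.55 or 0.72. A lift of signal under 20 by larger scaling factors is argued against as the whole cause. The rise was 0.43 with values under 20 raised to 20. This floor was set on values already scaled, so it cannot test the scaling of stronger values. An effect of anti-HER2 stays possible, though 2 tumours cannot show how far it would vary, the genes called fell to 0 under median rescaling (though with a median size of 1.14 left of 1.25) and with a block for the style of the sample code, the NK and type I interferon means fell to 0.32 and 0.16 under quantile normalization, and a separate handling of the arm was not tested.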

How the results depend on the processing

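Counts of called genes depended on the processing, and the cause was not tested unless named. No filter, housekeeping rescaling and endogenous genes only (added) left every count within 1.5 times. Named genes kept direction and side of the threshold in 5333 checks, were weaker in 660, stronger in 82 and reversed in 9; lists kept them in 361, were weaker in 128 and reversed in 2, where only lists called in the first place were counted. These reversals came with the cartridge block (added), which rests on 2 samples of open identity: Usp18 0.28 and Nod2 0.59 in ENT+CTLA4 against vehicle; Oas3 0.0367, Nod2 0.60 and Ifit1 0.0453 in ENT+PD1+CTLA4 against vehicle; Usp18 0.11, Tigit 0.0522, Nod2 0.57 and Nfkbia 0.0648 in ENT+PD1+CTLA4 against ENT+PD1; the type I interferon list in ENT+CTLA4 against vehicle (adjusted p = 0.783) and the housekeeping list in ENT+PD1+CTLA4 against ENT+PD1 (adjusted p = 0.975). That block left 0, 0 and 0 genes in these 3 comparisons and 0 in the F test, and gave the NK list in ENT+CTLA4 against vehicle an adjusted p = 0.924 and the neutrophil list there 0.783, the neutrophil list in ENT+CTLA4 against ENT 0.392 and the NK list in ENT+PD1+CTLA4 against ENT+PD1 0.975. It called the epithelial list lower in all 5 comparisons across cartridges (adjusted p = 0.000215 to 0.00183), 3 of which had it higher by camera without the block, and the macrophage list higher in ENT+CTLA4 and ENT+PD1+CTLA4 against ENT (0.00168 and 0.00965) and in ENT+PD1+CTLA4 against ENT+PD1 (0.0143, where it had been lower), none of them called before. It kept the macrophage lists of ENT+CTLA4 and ENT+PD1+CTLA4 against vehicle (adjusted p = 9.95e-05 and 0.000459), 2 of 2 genes of ENT+PD1 against ENT and 14 of 14 of ENT+CTLA4+HER2 against ENT+CTLA4, both within a cartridge. Within a cartridge the block leaves every log2 change as it was, so keeping these calls is no check on the cartridge. Only the estimate of the spread changed, as the repeat-titled pair joined the fit. With that changed spread, the block also called genes within a cartridge that the main fit did not. These were Alas1 in ENT+PD1 against ENT (limma adjusted p = 0.0481) and, with anti-HER2, Cxcl9 (0.0453), Bcl6 (0.0453), Ccl3 (0.0444), Cebpb (0.0462) and Klra2 (0.0453). Of these, Bcl6, Ccl3, Cebpb and Klra2 lie outside the naming rule for that comparison. Across cartridges the block's term is the repeat-titled pair minus all 4 ENT+PD1 tumours, including the immune-rich replicates 5 and 6. The calls it lost, reversed, kept or added there therefore do not separate treatment from cartridge. For ENT+CTLA4 against vehicle (9 genes), calls were 0 with the filter at 50, 3 with pseudocount 20, 0 with quantile normalization, 0 with the replicate block, 0 with the repeat-titled pair added, 0 in the compared groups alone, 21 in DESeq2 and 1 with the floor of 20 (added). For ENT+PD1+CTLA4 against vehicle (13), they were 1 with the filter at 50, 0 with median rescaling, 0 with quantile normalization, 0 with the replicate block, 4 with the code style block, 0 with the pair added, 0 in the groups alone, 0 in edgeR, 0 in DESeq2 and 2 with the floor. For ENT+PD1 against ENT (2), they were 4 without trend, 1 in DESeq2, and 0 with the filter at 50, pseudocount 20, median rescaling, quantile normalization, either block, the pair added, the groups alone, edgeR and the floor. For ENT+CTLA4 against ENT (0), they were 1 without trend, 46 in the groups alone and 15 in DESeq2. For ENT+PD1+CTLA4 against ENT+PD1 (20), they were 1 with the filter at 50, 0 with median rescaling, 1 (higher) with quantile normalization, 3 with the pair added, 0 in the groups alone, 1 in edgeR, 0 in DESeq2 and 7 with the floor. For ENT+CTLA4+HER2 against ENT+CTLA4 (14), they were 6 with the filter at 50, 0 with median rescaling, 0 with quantile normalization, 9 without trend, 0 with the replicate block, 0 with the code style block, 5 with the pair added, 0 in the groups alone, 23 in DESeq2 and 22 with the floor. For the F test (20), they were 1 with the filter at 50, 12 with pseudocount 20, 13 with median rescaling, 1 with quantile normalization, 6 with the replicate block, 0 with the pair added, 9 in edgeR, 48 in DESeq2 and 5 with the floor. List calls (22) were 34 with median rescaling, 9 with the code style block, 13 with the floor, 2 with an estimated correlation and 4 with fry.

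Sample weights moved many counts. The planned estimate, which did not converge, gave 1 gene in ENT against vehicle, 22 in ENT+PD1, 61 in ENT+CTLA4 and 74 in ENT+PD1+CTLA4 against vehicle, 152, 68 and 35 in these last 3 against ENT, 38 in ENT+PD1+CTLA4 against ENT+PD1, 7 for the interaction and 170 for the F test. Weights gene by gene, chosen after these counts had been seen, gave 1, 59 and 49 in ENT, ENT+CTLA4 and ENT+PD1+CTLA4 against vehicle, 0, 64 and 17 in ENT+PD1, ENT+CTLA4 and ENT+PD1+CTLA4 against ENT, 7 in ENT+PD1+CTLA4 against ENT+PD1, 5 with anti-HER2 and 101 for the F test. With each sample left out in turn, calls ran from 0 (vehicle 5, vehicle 1) to 22 (vehicle 3) in ENT+CTLA4 against vehicle, with 2 without vehicle 2, 5 without ENT+CTLA4 2 and 3 without 5. They ran from 0 (vehicle 5, vehicle 1, ENT+PD1+CTLA4 5) to 18 (vehicle 3) in ENT+PD1+CTLA4 against vehicle, with 1 without vehicle 2, 6 without ENT+PD1+CTLA4 6 and 1 without 2. They ran from 0 (ENT 1, 2, 4; ENT+PD1 5, 6) to 26 (ENT+PD1 1) in ENT+PD1 against ENT, with 9 without ENT+PD1 2, and from 2 (ENT+PD1 5) to 69 (ENT+PD1 2) in ENT+PD1+CTLA4 against ENT+PD1, with 11 without ENT+PD1 1 or 6, 4 without ENT+PD1+CTLA4 5, 41 without 1 and 9 without 2. With anti-HER2 they ran from 0 (ENT+CTLA4 5, 6) to 23 (ENT+CTLA4+HER2 1), with 6 without ENT+CTLA4 2 or ENT+CTLA4+HER2 2, the lone sample assumed to vary like the other groups. The F test ran from 6 (vehicle 2) to 57 (ENT+PD1 2), with 16 of 20 fits moving over 1.5 times: without vehicle 5, 1 and 3 it gave 13, 8 and 36, without ENT 1 and 4 13 and 12, without ENT+PD1 5 or 6 8 each, without ENT+CTLA4 2, 5 and 6 7, 11 and 7, and without ENT+PD1+CTLA4 5, 6, 1 and 2 8, 12, 40 and 12. List calls ran from 14 (ENT+PD1 6) to 28 (ENT+PD1 1). Counts of 0 ran from 0 to 1 in ENT+CTLA4 against ENT (ENT+CTLA4 6), ENT+PD1+CTLA4 against ENT (ENT+PD1+CTLA4 1) and the interaction (ENT+PD1 1, 2), and stayed 0 elsewhere. With the filter at 50, which left 466 genes, few calls remained because most called genes were weak (14 of the 18 called in the anti-CTLA-4 arms against vehicle had a mean under 50).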

Other observations

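The splits of the samples were set before their results were seen, and the tests of the repeat-titled pair were added after the data were seen. Neutrophil genes differed most between single tumours of the anti-HER2 arm, with list scores of 0.81 and 2.18 relative to vehicle (mean 1.49, SD 0.971), where ENT+CTLA4 lay at 0.43 ± 0.098 (n = 4). S100a8, of granulocytes, reached 6723 ± 7234 in that arm. T cell genes were high in single tumours of other arms: ENT+PD1+CTLA4 replicate 1 had a score of 3.02 in a group with a mean of 0.38 (SD 1.79), and an ENT+CTLA4 tumour 2.02 in a group with a mean of 0.08 (SD 1.36). MHC class II scores in ENT+PD1 ran from −0.10 to 2.01. NK scores were −0.63 (SD 0.205) in ENT+CTLA4, −0.66 (SD 0.564) in ENT+PD1+CTLA4, −0.70 in the repeat-titled pair and 0.29 in ENT+CTLA4+HER2.

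The repeat-titled pair differed from the samples whose titles it repeats. Between a repeat and its namesake the squared difference per gene, in units of counting error, was 18.0 and 32.6 over 308 genes. For 32 pairs of samples within a group it ran from 8.23 to 318, with 18.7 between the repeat-titled samples themselves. All pairs within a group share a cartridge, while a repeat and its namesake do not, so the values are not alike. The namesake was the 4th and 9th nearest of the 23 other samples, the nearest being vehicle replicate 1 and ENT+CTLA4 replicate 2. Against ENT+PD1 limma called 9 genes (161 at unadjusted p under 0.05): Igf2r, a receptor that clears growth factor, was higher (0.66), and Bst2 (−0.76), the chemokine receptor Cxcr3 (−1.94), the receptors Il11ra1 and Il22ra2 (−1.55 each), Nod2 (−1.63), the synthetase Oas2 (−1.84), the ligand Tnfsf18 (−1.55) and Usp18 (−1.50) were lower. Against ENT+PD1+CTLA4 and ENT+CTLA4 it called 0 genes (32 and 44 at unadjusted p under 0.05). Whether the pair are repeat runs, other tumours or another arm stays open.

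Whether chance could give the counts of calls was tested by splitting the 8 samples of a comparison in every way into 4 and 4. No other split gave as many calls for ENT+CTLA4 against vehicle (1 of 35 splits as large, the real one with 9, highest other 1), ENT+PD1+CTLA4 against vehicle (1 of 35, 13, highest other 6) and ENT+PD1 against ENT (1 of 35, 2, highest other 0). A share of 1 of 35 is the smallest that these splits can give. No adjustment was made over the comparisons split, so chance is made less likely but is not excluded. For the comparisons with vehicle the splits do not tell treatment from cartridge. For the F test no other regrouping gave as many either (1 of 100 regroupings as large, 20, highest other 4). Those regroupings mix the cartridges, so a difference between cartridges alone could give this. Chance stays open for ENT+PD1+CTLA4 against ENT+PD1, where 4 of 35 splits were as large (20, highest other 244), and for the list calls (68 of 100 regroupings, 22, highest other 49). For the comparisons with 0 calls the splits decide nothing, since every split is as large by construction (35 of 35), and the highest other was 0 in ENT against vehicle and ENT+CTLA4 against ENT, 1 in ENT+PD1+CTLA4 against ENT and against ENT+CTLA4, and 76 in ENT+PD1 against vehicle, and for the interaction 100 of 100 regroupings (0, highest other 110). The splits with 244 and 76 calls point to a structure of the samples that is larger than the arms: the first set ENT+PD1 replicates 5 and 6 with ENT+PD1+CTLA4 replicates 5 and 1, and the second ENT+PD1 replicates 1 and 2 with vehicle replicates 1 and 2.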
